A study of Mus musculus with 6 samples.

How the data were processed

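Poly-A selected RNA from frozen mouse small intestine was sequenced in 6 libraries, 3 labelled control and 3 labelled model, per the labels' protocols. Reads were processed with FastQC, Trimmomatic, STAR and featureCounts against genome build GRCm39, per the submitters' processing notes, which give no versions or settings. The annotation and the strand setting are not given in the sources used here. The authors deposited 1 table of raw read counts, whole numbers per gene and library, named by gene symbol. Each of its 6 columns was matched to a sample by the library name in the labels, and 0 columns were left unmatched. Because multi-mapping settings are not given, values of genes with near-identical copies (heat shock Hspa1a and Hspa1b, defensins, acyl-CoA thioesterases, histocompatibility and immunoglobulin genes) are uncertain, and without a known strand setting reads of overlapping and antisense genes cannot be told apart. Several genes, such as Xist, Igkc, Ms4a1 and Cela2a, are listed at 0 in all 6 libraries, which was not read as absence of their transcripts. The mitochondrial genes COX2, COX3, ATP6 and ATP8 had far fewer counts than COX1 in each library and are likewise uncertain. The table gives no coordinates and the reference at hand is of another build (GRCm38), so none are printed. That reference was used only for the length and GC content of transcripts, which were matched by symbol for 15367 of the tested genes (96.6%).

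Library totals were 45285564, 37608414 and 36158165 counts in control 1, 2 and 3 and 35007515, 43664883 and 36182282 counts in model 1, 2 and 3. Genes were kept by edgeR's filterByExpr, leaving 15904 of 33017 genes with at least 99.6% of the counts of each library. Libraries were scaled by TMM. The main test was edgeR's quasi-likelihood F test with robust dispersion on the deposited counts, with the group as the only term, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called (R 4.3.3, edgeR 4.0.16). SEs are the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 40.7%. Counts of each pair of libraries within a group differed far beyond sampling noise (chi-square per degree of freedom between 110.9 and 542.7), so no library was treated as a duplicate.

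The tests, the rule for named genes and 47 lists of genes (epithelial, immune and other cell types, segments, and pathways) were fixed before the data were examined. Of 669 list genes 663 are in the table and 585 were tested. The 42 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on voom log2 CPM at its preset correlation of 0.01, adjusted over the lists, then with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction. With the preset correlation 21 lists were called, 13 higher and 8 lower. With an estimated correlation 0 were called (smallest adjusted p 0.51, with 2 lists, p53 targets and smooth muscle, at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p 0.38). The medians of lists, and the numbers of members higher or lower, are of the differences in mean voom log2 CPM that camera uses, while fold changes of single genes are edgeR's. The numbers of members were first taken from edgeR and were changed to voom after the results were seen, so that they match the medians. The change was largest for type I interferon response genes, with 11 of 25 higher in place of 19, for interferon gamma response genes, with 6 of 11 in place of 11, and for macrophage markers, with 8 of 13 in place of 5. The median turned its sign between the scales for type I interferon, tuft cell, macrophage, and mast cell and eosinophil lists. The report gives both medians for each tested list in which they differ in sign or by over 1.5 times. The median and the mean of a list differed in sign for 2 tested lists (macrophage markers, and mast cell and eosinophil markers). The median and camera's direction differed for 4 lists, the same 2 and those of junction and type I interferon response genes, none of which was called. Named are the 10 genes with the smallest p, since fewer than 10 passed the threshold, the 2 most abundant members of each list, since none passed, and 15 fixed genes (Tnf, Il1b, Il6, Il10, Ifng, Cdkn1a, Lgr5, Mki67, Lyz1, Muc2, Tjp1, Ocln, Cldn1, Nfkbia and Tlr4). Some genes that this rule names are not reported here. Other genes are named as chosen after their values were seen, or, for segment, pancreas and B cell genes, as members of the fixed lists that set single libraries apart.

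Alternatives were other scalings (RLE, upper quartile, library size alone), DESeq2 1.42.0, limma-voom, other filters on low counts (none, or at least 5 CPM in at least 3 libraries), a non-robust dispersion, a log2 fold change of at least 1 as well, the replicate number as a block and each library left out in turn. After seeing the data, voom with library quality weights, removal of each library's lowess trend (span 0.3) of log2 CPM with transcript length, and fits without control 3 and either model 1 or model 3 were added. The procedure was tested on simulated counts drawn for the 15904 genes with the observed means, spread and library sizes. In them 200 genes were changed, drawn only from genes with a mean of at least 5 CPM. Of these 200 edgeR recovered 0% at 2-fold, 77% at 4-fold and 95% at 8-fold, with 0, 6 and 7 false calls. Recovery of genes at lower levels was not tested. The simulation has no structure shared by genes within a library, which the real libraries have. A simulated list of 15 genes, also of at least 5 CPM, changed 2-fold was called by camera and 0 other lists were.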

Results

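Messenger RNA was sequenced from the small intestine of mice in 2 groups. The labels call them control and model, with 3 libraries in each (control 1 to 3 and model 1 to 3). The title of the series speaks of intestinal immune disorder under simulated microgravity and radiation and of a protective compound. The design text describes a comparison of both groups for the joint effect of the 2 factors, and no library used here is labelled as given the compound. The question addressed was therefore which intestinal transcripts differed between control and model tissue. The deposited table gave whole-number read counts for 33017 genes, with library totals between 35007515 and 45285564 counts. Of these genes, 11665 were at 0 in all 6 libraries and 15904 had enough counts to be tested. The labels do not say that the libraries of a group came from different animals, so p-values measure only the spread between these libraries, which may be technical. Levels below are CPM, read counts relative to the TMM-scaled library total, given as mean ± SD with n = 3 per group, and log2 fold changes are model against control with their standard error (SE).

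No single gene passed the test between model and control. Among the 10 genes with the smallest p, none of which passed, 7 had higher and 3 had lower values in the model libraries. Nr1d1, a repressor in the circadian clock, measured 3.38 ± 1.45 CPM in control and 13.5 ± 0.881 CPM in model tissue, a log2 fold change of 2.0 (SE 0.34). Acot1, an acyl-CoA thioesterase, had 2.81 ± 0.763 CPM in control and 14.2 ± 6.23 CPM in model tissue (log2 fold change 2.33, SE 0.40), although reads shared with its close paralogs make this value uncertain. The transmembrane mucin Muc1 had a log2 fold change of 3.44 (SE 0.65) and the secreted phosphoprotein Spp1 one of 3.46 (SE 0.75), both from control means under 1 CPM. Efna1, an ephrin ligand, measured 56.8 ± 4.89 CPM in control and 111 ± 18.7 CPM in model tissue, and the endoplasmic reticulum co-chaperone Dnajb9 measured 53.8 ± 8.82 and 125 ± 33.0 CPM. Lower in all 3 model libraries were the muscle filamin Flnc (log2 fold change -1.21, SE 0.26), the surface glycoprotein Cd109 (-2.75, SE 0.60) and the matrix proteoglycan Optc (-1.83, SE 0.40).

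**Figure D1:**
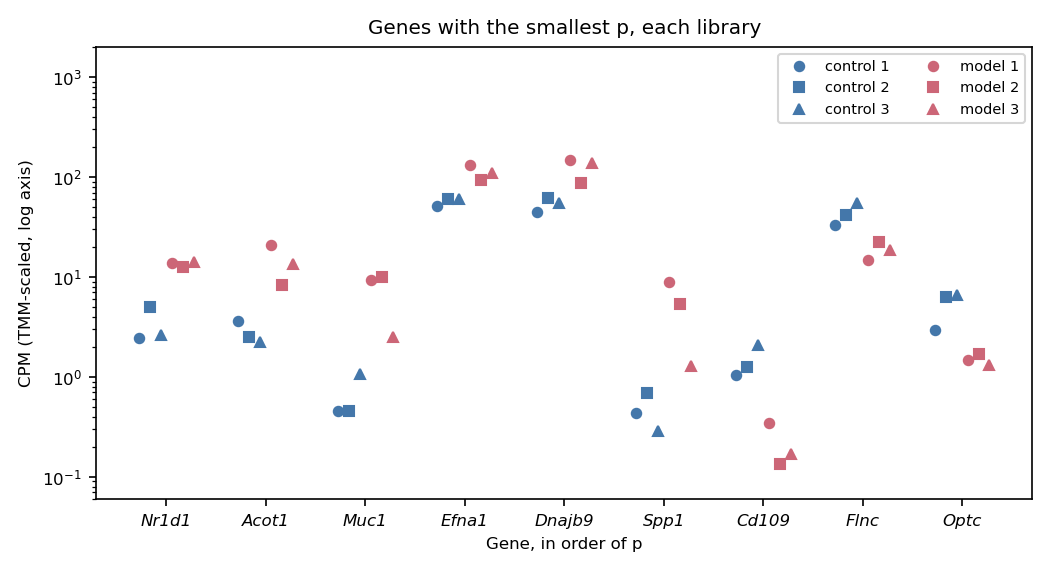
Of the 10 genes with the smallest p, 9 are drawn in order of p on the x axis, with CPM on a log y axis; each point is 1 library, blue for control and red for model. The groups do not overlap for any of the 9 genes, and none of them passed the adjusted threshold.

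The smallest Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test was 0.851, and 0 genes were called at 0.05. At an unadjusted p under 0.05 edgeR gave 765 genes, 290 higher and 475 lower, where chance alone would give 795. Without control 3 that number was 377 and the balance turned, with 61.3% of these genes higher against 37.9% with all libraries. The groups did not overlap for 1758 genes, 11.1% of those tested, where chance gives 10%. DESeq2's Wald test, run as an alternative, called 25 genes, 18 higher and 7 lower. Of these, 5 were also called in each DESeq2 fit that left out 1 library, and they are named here after their values were seen: Muc1, Nr1d1, Acot1, Hdc and Gsdmc4. Hdc, the histidine decarboxylase of mast cells and other histamine-producing cells, measured 1.74 ± 0.395 CPM in control and 13.2 ± 11.5 CPM in model tissue. Gsdmc4, a gasdermin with close paralogs, was at 9.66, 6.49 and 79.6 CPM in the control libraries and at 1.80, 1.45 and 1.65 CPM in the model libraries. The number of DESeq2 calls depended on the libraries used: it was 101 without control 2, 87 without model 2 and 47 without control 1.

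The list of fatty acid oxidation and PPAR target genes, which serve the breakdown of fatty acids, had a median log2 fold change of 1.35, with 15 of 16 tested members higher in the model group. Among its abundant members was Hadha, at 363 ± 133 CPM in control and 460 ± 68.4 CPM in model tissue. Pdk4, a kinase that restrains glucose oxidation, named after its values were seen, had 50.5 ± 34.9 and 266 ± 151 CPM. In the opposite direction, 18 of 19 cholesterol synthesis genes were lower in the model group, with a median of -0.83. Its most abundant members were Srebf2, the transcription factor of the pathway (log2 fold change -0.54, SE 0.25), and the sterol carrier Stard4 (-0.57, SE 0.31), and 8 of the 19 genes were lower in every model library than in every control library. Among the latter, and chosen after seeing the values, Hmgcs1 had a log2 fold change of -1.13 (SE 0.38). The limma test camera with its preset correlation gave adjusted p = 9.6e-10 for the fatty acid list and 1.0e-08 for the cholesterol list, and both had an adjusted p = 0.51 with an estimated correlation between genes. No member of either list was called over all genes tested, while adjusted over the list alone 2 fatty acid genes, Acot1 among them, and 0 cholesterol genes were. Control 3 set much of the size of the fatty acid result: without it the median was 0.46, without control 3 and model 1 it was 0.22, and the median of edgeR's fold changes was 0.93. The cholesterol list was highest in control 3, with a median deviation from the gene means of 1.05, and lowest in model 1, with -0.62, and its median fold change was -0.57 without control 3 and -0.42 without both. The fits without 2 libraries were chosen after the data were seen.

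Genes induced by glucocorticoids, the steroid hormones of the stress response, had a median log2 fold change of 1.12, and 9 of 10 tested members were higher in the model group. The most abundant were the kinase gene Sgk1, at 371 ± 214 CPM in control and 1070 ± 664 CPM in model tissue, and Tsc22d3, at 132 ± 36.9 and 251 ± 163 CPM. Named after their values were seen, Fkbp5, a co-chaperone of the glucocorticoid receptor, measured 56.1 ± 26.8 and 308 ± 172 CPM, and the metallothionein Mt1 measured 42.5 ± 17.6 and 116 ± 29.3 CPM. The model libraries were not alike: the list's median deviation from the gene means was 1.11 in model 1 and 0.76 in model 3, but -0.20 in model 2, which lay between the control values of -0.63 and -0.09. Camera gave adjusted p = 3.3e-05 with the preset correlation and adjusted p = 0.51 with an estimated correlation. Adjusted over the list alone, 3 members were called, against 0 over all genes.

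Heat shock genes had 9 of 10 members higher in the model group and a median of 0.35, although the list's median deviation in model 3, -0.20, lay among the control values. Hspa8, the constitutive chaperone, measured 1310 ± 178 and 1940 ± 406 CPM, Hsp90aa1 had a log2 fold change of 0.42 (SE 0.24), and, chosen after seeing the values, Hsph1 had one of 1.13 (SE 0.27). Of 24 target genes of p53, the transcription factor activated by DNA damage, 20 were higher, with a median of 0.22. The cell cycle inhibitor Cdkn1a measured 166 ± 38.6 and 261 ± 107 CPM and Perp 186 ± 23.2 and 227 ± 108 CPM, both with overlapping groups. Mdm2, the ubiquitin ligase of p53, named after its values were seen, had 64.9 ± 7.55 CPM in control and 122 ± 41.6 CPM in model tissue and did not overlap. Endoplasmic reticulum stress genes had a median of 0.21, with Hspa5 at a log2 fold change of 0.31 (SE 0.28) and Calr at -0.12 (SE 0.28). Their median deviation in model 3, -0.095, lay among the control values (-0.20 to 0.031). Oxidative stress response genes had a median of 0.44, with Prdx1 at 0.42 (SE 0.45) and Txnrd1 at 0.43 (SE 0.30). Here the median deviation of control 2, 0.24, lay above those of model 2 (0.091) and model 3 (0.061). Camera's adjusted p was 0.00046 for heat shock, 0.0019 for p53 targets, 0.0079 for endoplasmic reticulum stress and 0.015 for oxidative stress. With an estimated correlation the adjusted p was 0.52 for heat shock and 0.51 for the other 3 lists. Adjusted over the list alone, 2 heat shock genes (Hspa1b and Hsph1, of which the former shares reads with a near-identical copy), 1 endoplasmic reticulum gene (Dnajb9) and 0 p53 targets were called. The p53 median was 0.096 without control 2 and the heat shock median 0.20 without model 1 and 0.55 without model 3. The call of the oxidative stress list was lost without control 3 (0.19) and without model 1 (0.28), and that of the endoplasmic reticulum list without control 1 (0.18) and without model 2 (0.13), with a median of 0.35 without model 3. With scaling by library size alone all 4 lists kept their call, with medians of 0.14 for heat shock, 0.018 for p53 targets, 0.010 for endoplasmic reticulum stress and 0.22 for oxidative stress.

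**Figure D2:**
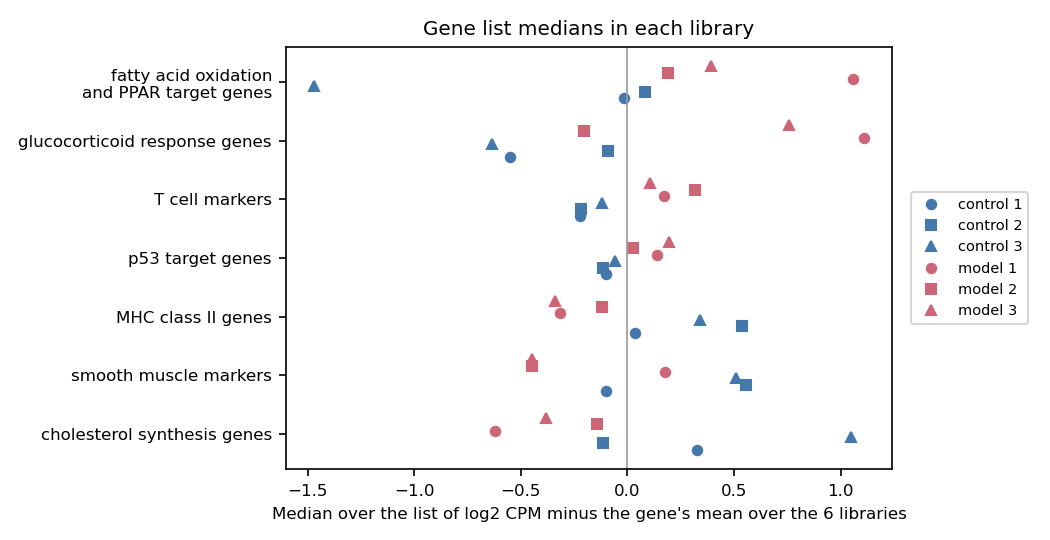
Gene lists on the y axis against the median, over a list's genes, of log2 CPM minus the gene's mean over the 6 libraries; each point is 1 library, blue for control and red for model. The 7 lists drawn kept their camera call without each single library, without 2 pairs of libraries and with a correction for transcript length, all at the preset correlation, and all 7 had adjusted p = 0.51 with an estimated correlation. For glucocorticoid response genes model 2 lies at -0.20, among the control libraries, and for smooth muscle markers model 1, at 0.18, lies above control 1, at -0.10.

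Of 26 cell cycle genes 22 were lower in the model group, with a median of -0.23, and the proliferation markers Mki67 and Top2a had log2 fold changes of -0.32 (SE 0.30) and -0.48 (SE 0.29). Of 15 intestinal stem cell markers 11 were lower, with a median of -0.30. Their most abundant members were Olfm4 (log2 fold change 0.11, SE 0.29) and Slc12a2 (-0.29, SE 0.24), and the stem cell receptor Lgr5 measured 13.9 ± 8.04 CPM in control and 6.35 ± 0.422 CPM in model tissue, with overlapping groups. Camera gave adjusted p = 0.011 for the cell cycle and 0.021 for stem cell markers, and with an estimated correlation adjusted p = 0.67 and 0.51. The model libraries were not alike: the median deviation of cell cycle genes was -0.45 in model 1 but 0.198 in model 2, above all 3 control libraries (0.0847 to 0.193), and that of stem cell markers was 0.092 in model 2, above control 2 at -0.0040. The cell cycle call was lost without control 1 (median -0.17), control 2 (-0.25), model 1 (-0.11) or model 3 (-0.24), and the median was -0.40 without model 2. The stem cell call was lost without control 1 (-0.33) or model 3 (-0.37), and the median was -0.19 without model 1 and -0.14, still called, with the trend of each library with transcript length removed. With scaling by library size alone the medians were -0.43 for cell cycle and -0.50 for stem cell genes.

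All 8 MHC class II genes, which present antigen to helper T cells, were lower in the model group, with a median of -0.53. Cd74, the invariant chain, measured 1150 ± 197 CPM in control and 779 ± 61.7 CPM in model tissue and H2-Ab1 465 ± 97.8 and 334 ± 34.4 CPM, and 4 of the 8 genes were lower in every model library than in every control library. T cell markers had 13 of 15 members higher and a median of 0.38. The co-receptor gene Cd8a measured 34.9 ± 16.5 and 58.6 ± 10.7 CPM, and the T cell receptor kinase gene Lck 22.8 ± 0.725 and 30.3 ± 1.81 CPM. Cytotoxic lymphocyte markers had a median of 0.49, with the granzyme genes Gzma at a log2 fold change of 0.85 (SE 0.61) and Gzmb at 0.95 (SE 0.49). The libraries overlapped, with a median deviation of 0.20 in control 2, 0.15 in model 1 and -0.094 in model 3. MHC class I genes had a median of 0.37, with H2-K1 at 0.46 (SE 0.38) and H2-D1 at 0.27 (SE 0.28), values that reads shared within the family make uncertain. Their median deviation in model 3, -0.21, lay below control 1 (0.12) and control 2 (0.29). All 13 B cell markers were lower, with a median of -1.66 (-0.84 for edgeR's fold changes), but the groups overlapped for each of them: Ighd was at 68.8 CPM in control 3 and 32.8 CPM in model 3 and at most 4.17 CPM elsewhere, and Cd22 at 44.5 and 28.6 CPM and at most 7.86 CPM elsewhere. Camera's adjusted p was 0.00016 for MHC class II, 0.0012 for T cell, 0.014 for cytotoxic, 0.016 for MHC class I and 0.039 for B cell genes. With an estimated correlation the adjusted p was 0.51, 0.51, 0.52, 0.69 and 0.75 in the same order. The cytotoxic call was lost without control 3 (median 0.27) or model 2 (0.50). The MHC class I call was lost without control 3 (0.032), model 1 (0.22) or model 2 (0.42), and its median was 0.58 without control 2 and also without model 3. The B cell call was lost without control 1 (-2.08), control 3 (-0.36), model 1 (-0.50) or model 2 (-0.41), and the median was -3.35 without model 3. With scaling by library size alone the B cell call was lost (-1.89, adjusted p = 0.33), and the medians were 0.19 for T cell, 0.28 for cytotoxic and 0.16 for MHC class I genes, all still called.

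Inflammatory genes were not called as a group with all 6 libraries. The list of inflammatory cytokines and NF-kB genes had 13 of 23 members higher and a median of 0.064 (camera adjusted p = 0.16), a median that was negative when libraries were scaled by size alone. Nfkb1 measured 129 ± 9.41 and 135 ± 2.46 CPM and Casp1 122 ± 10.8 and 113 ± 38.4 CPM. The list was called without control 3 (median 0.17, adjusted p = 0.021 by camera) and without model 1 (0.33, adjusted p = 0.041). Among single cytokines, Tnf measured 1.26 ± 0.651 and 1.33 ± 1.29 CPM, Il1b 1.22 ± 0.62 and 1.44 ± 0.805 CPM and Il10 0.298 ± 0.139 and 0.494 ± 0.451 CPM. Il6 and Ifng, at means of 0.14 and 0.188 CPM in control tissue, were too low to be tested. The NF-kB inhibitor gene Nfkbia had a log2 fold change of 0.22 (SE 0.22) and the endotoxin receptor gene Tlr4 one of -0.82 (SE 0.60). Of the 15 genes fixed for naming, 13 could be tested and 0 passed when adjusted over these genes alone (smallest edgeR adjusted p = 0.462).

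Other immune lists were not called by camera. Interferon gamma response genes had 6 of 11 members higher and a median of 0.13 (adjusted p = 0.26), against 11 higher and a median of 0.26 for edgeR's fold changes, with Irf1 at a log2 fold change of 0.46 (SE 0.27) and Irgm2 at 0.26 (SE 0.52). Type I interferon response genes had 11 of 25 members higher and a median of -0.019 (adjusted p = 0.74), against 19 higher and a median of 0.099 for edgeR's fold changes, with Ifit1bl1 at -0.94 (SE 0.74) and Oasl2 at 0.22 (SE 0.41). Both interferon lists were called in opposite directions depending on which model library was left out: the type I median was -0.36 without model 2 and 0.22 without model 3, and the gamma median was -0.54 without model 2, 0.29 without model 3 and 0.43 without model 1. Innate sensing genes had a median of -0.31 (adjusted p = 0.29), with Nlrp6 at 0.24 (SE 0.30) and Irak4 at 0.34 (SE 0.20), and were called without model 2 (-0.60). Antimicrobial defence genes had a median of -0.38 (-0.60 for edgeR's fold changes, adjusted p = 0.52 by camera). Its members included the antibody transporter gene Pigr, at 6500 ± 2750 and 7320 ± 787 CPM, and the lectin gene Reg3b, at 11100 CPM in control 3, 3960 CPM in model 2 and 496 to 1400 CPM in the other 4 libraries. Plasma cell markers had a median of 0.25 (adjusted p = 0.31), with Igha at a log2 fold change of 0.37 (SE 0.36) and Jchain at 0.26 (SE 0.29), and were called without control 3 (0.30). Macrophage markers had a median of 0.071 (-0.050 for edgeR's fold changes, adjusted p = 1 by camera), with Lyz2 at -0.059 (SE 0.36) and Csf1r at -0.037 (SE 0.36), and were called lower without control 2 (-0.30). Dendritic cell markers had a median of -0.17 (-0.29 for edgeR's fold changes, adjusted p = 0.42 by camera), with Itgax at -0.31 (SE 0.34) and Zbtb46 at -0.49 (SE 0.42). Peyer's patch follicle genes had a median of -0.097 (-0.19 for edgeR's fold changes, adjusted p = 0.80 by camera). Its member Spib measured 18.6 ± 12.6 and 15.9 ± 14.5 CPM, and Gp2, which the exocrine pancreas also makes, was at 101 CPM in model 3 and at most 1.38 CPM elsewhere. Mast cell and eosinophil markers had a median of -0.0057 (0.039 for edgeR's fold changes, adjusted p = 0.65 by camera), with the receptor gene Kit at a log2 fold change of -1.07 (SE 0.40) and Hdc at 2.93 (SE 0.64), the latter called when adjusted over the list alone. Only 2 of 12 neutrophil markers, Csf3r at -0.20 (SE 0.52) and Ltf at 0.82 (SE 0.68), had enough counts, so this list was not tested.

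All 10 tested markers of smooth muscle, which surrounds the mucosa in the gut wall, were lower in the model group, with a median of -0.74. The libraries overlapped, with a median deviation of -0.10 in control 1 and 0.18 in model 1. The myosin gene Myh11 measured 709 ± 156 CPM in control and 379 ± 85.4 CPM in model tissue, and Acta2 353 ± 106 and 211 ± 86.6 CPM. Fibroblast and matrix genes had a median of -0.60, with the collagen genes Col3a1 at a log2 fold change of -0.78 (SE 0.55) and Col1a1 at -0.74 (SE 0.61). Enteric neuron and glia markers had a median of -0.41 (-0.25 for edgeR's fold changes), with the neuropeptide gene Vip at -0.0027 (SE 0.39) and the receptor gene Ret at -0.63 (SE 0.32). Camera gave adjusted p = 4.0e-06 for smooth muscle and 0.039 for the other 2 lists, and with an estimated correlation adjusted p = 0.51, 0.75 for fibroblasts and 0.53 for neurons and glia. The fibroblast call was lost without control 1 (median -0.33), control 3 (-0.23), model 1 (-0.15) or model 3 (-0.69), and its median was -1.20 without control 2 and -0.91 without model 2. It was also lost with the length trend removed (median -0.34, adjusted p = 0.052) and with scaling by library size alone (-0.80, adjusted p = 0.17). The neuron and glia call was lost without control 2 (-0.29), control 3 (-0.27), model 2 (-0.060) or model 3 (-0.38), and with scaling by library size alone (-0.57, adjusted p = 0.058). Endothelial markers had a median of 0.054 (camera adjusted p = 0.25), with Plvap at 0.57 (SE 0.32) and Pecam1 at -0.10 (SE 0.37). They were called without control 1 (0.34) and without model 1 (0.20). Adipocyte markers had a median of -1.61 with all libraries (-2.57 for edgeR's fold changes, camera adjusted p = 0.42), which was -0.21 without control 3, -0.56 without model 2 and -2.74 without control 2, and control 3 stood highest, with a median deviation of 3.08. Of its members, the lipid droplet gene Cidec, also active in enterocytes, measured 56.0 ± 29.5 and 140 ± 42.7 CPM and Fabp4 16.4 ± 16.5 and 11.1 ± 4.44 CPM. The 4 tested erythroid genes, too few for the list test, were all lower, with Hbb-bs at -0.63 (SE 0.41) and Hba-a1 at -0.50 (SE 0.41).

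Absorptive enterocyte markers had 19 of 21 members higher in the model group and a median of 1.01 (0.77 for edgeR's fold changes). The apolipoprotein genes Apoa1 and Apob had log2 fold changes of 1.04 (SE 0.55) and 0.43 (SE 0.40). Xenobiotic metabolism genes had a median of 1.35 (0.67 for edgeR's fold changes), with the cytochrome gene Cyp3a11 at 861 ± 742 and 3420 ± 2290 CPM and Ugt2b34 at 809 ± 464 and 1140 ± 317 CPM. Mitochondrially encoded genes had a median of 0.45, with COX1 at 0.37 (SE 0.46) and CYTB at 0.34 (SE 0.44). All 8 genes typical of the proximal small intestine were higher, with a median of 2.56 (0.68 for edgeR's fold changes), although Apoa4 had a log2 fold change of 0.93 (SE 1.24) and lactase, Lct, one of 0.095 (SE 1.66). Camera gave adjusted p = 1.3e-05 for enterocytes, 0.00061 for xenobiotic metabolism, 0.0023 for proximal genes and 0.0056 for mitochondrial genes. With an estimated correlation the adjusted p was 0.52, 0.52, 0.53 and 0.60 in the same order. These 4 results rested on control 3 for their size. Without it the medians were 0.29 for enterocytes, 0.17 for xenobiotic metabolism, 0.19 for proximal genes and 0.18 for mitochondrial genes, and the calls of the last 2 lists were lost. The proximal median was also 3.87 without control 1, and the mitochondrial median 0.83 without control 2, 0.26 without model 1 and 0.25 with scaling by library size alone. The 4 tested distal genes were all lower in the model group, with Slc51a at -0.50 (SE 0.56) and Nr1h4 at -0.70 (SE 0.51), and the list was not called in the 4 fits without 1 library in which enough members were tested.

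**Figure D3:**
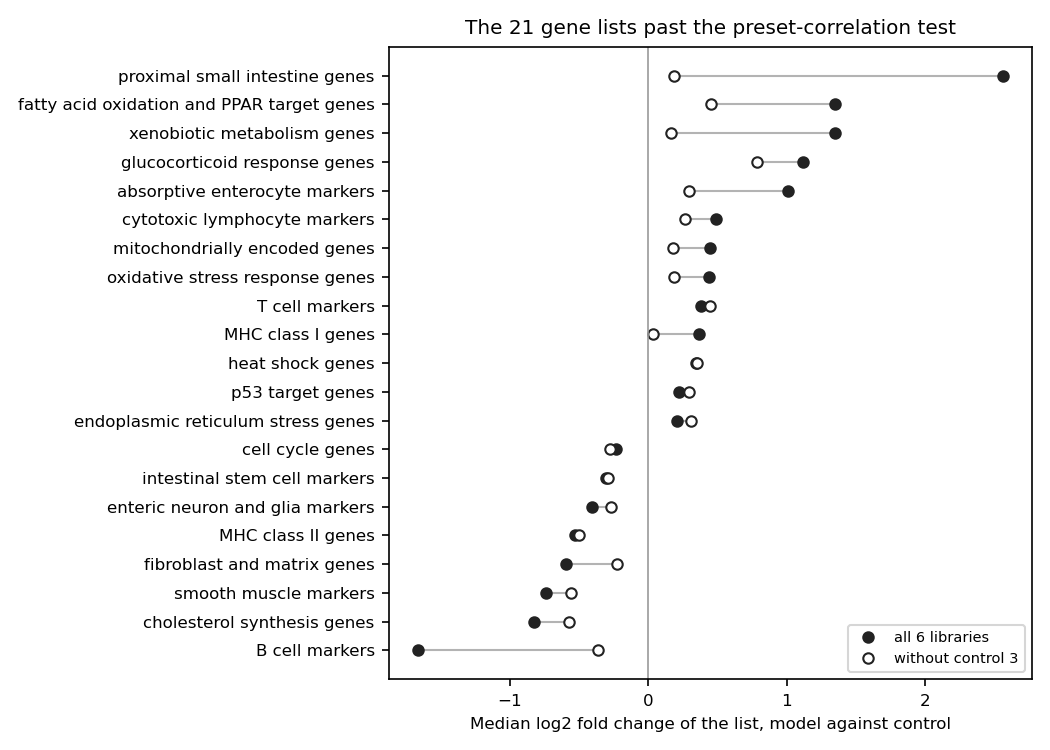
The 21 gene lists past the camera test with its preset correlation on the y axis, against their median log2 fold change, model against control; filled points use all 6 libraries and open points leave out control 3. The proximal small intestine median goes from 2.56 to 0.19, and that of glucocorticoid response genes from 1.12 to 0.79.

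Control 3 differed from the other 5 libraries in genes that mark position along the intestine. Fabp6, the bile acid binding protein of the ileum, was at 1170 CPM in control 3 and at most 0.285 CPM elsewhere, and the ileal bile acid transporter gene Slc10a2 was at 648 CPM and at most 4.60 CPM elsewhere. Lct was at 0.997 CPM in control 3 and between 610 and 2250 CPM in the other libraries, and Fabp1, the fatty acid binding protein of the proximal intestine, was at 0.926 CPM against 822 to 1520 CPM. The first principal component, with 46.3% of the variance, had control 3 at one end and model 1 at the other. Model 3 held abundant transcripts of digestive enzymes of the exocrine pancreas, with Ctrb1 at 1890 CPM and Pnlip at 1020 CPM. Model 1 held them at a far lower level, 4.12 and 2.42 CPM, and the remaining libraries at most at 0.309 and 0.261 CPM. The 4 tested pancreatic acinar genes were too few for the list test, and 3 were called when adjusted over the list alone. In the 4 fits without 1 library in which enough members were tested, camera called the list without model 2 (median 8.83, adjusted p = 0.0040) and not without control 1, control 2 or control 3. Control 3 and model 3 shared high B cell transcripts, as given above for Ighd and Cd22. Peyer's patch follicle genes were also highest in these libraries, with median deviations of 1.39 in control 3 and 1.49 in model 3. In the other libraries that median was at most -0.0090. In model 1 long transcripts were low: over the genes with a known transcript length, the Spearman correlation across genes between length and the library's deviation from the gene means was -0.41 (genes are not independent replicates). In the other 5 libraries this correlation lay between -0.065 and 0.25 and was highest in control 3. Control 3 and model 1 were thus the ends of both this correlation and the first principal component. That component cannot be read as intestinal position alone.

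**Figure D4:**
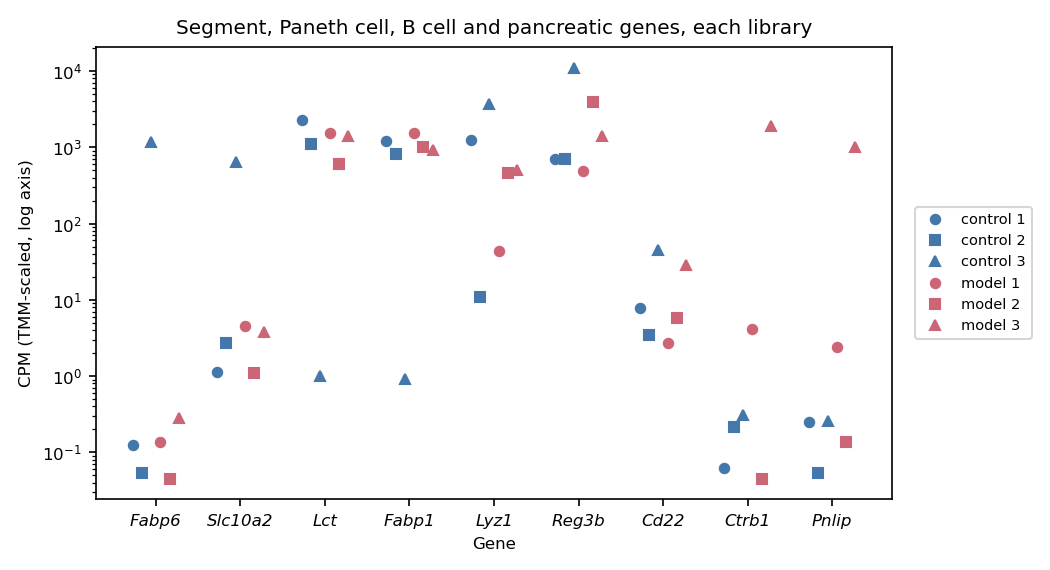
CPM on a log y axis of 9 genes of intestinal segments, Paneth cells, B cells and pancreas; each point is 1 library, blue for control and red for model. Control 3 holds Fabp6 at 1170 CPM and Lct at 0.997 CPM, and model 3 holds Ctrb1 at 1890 CPM.

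**Figure D5:**
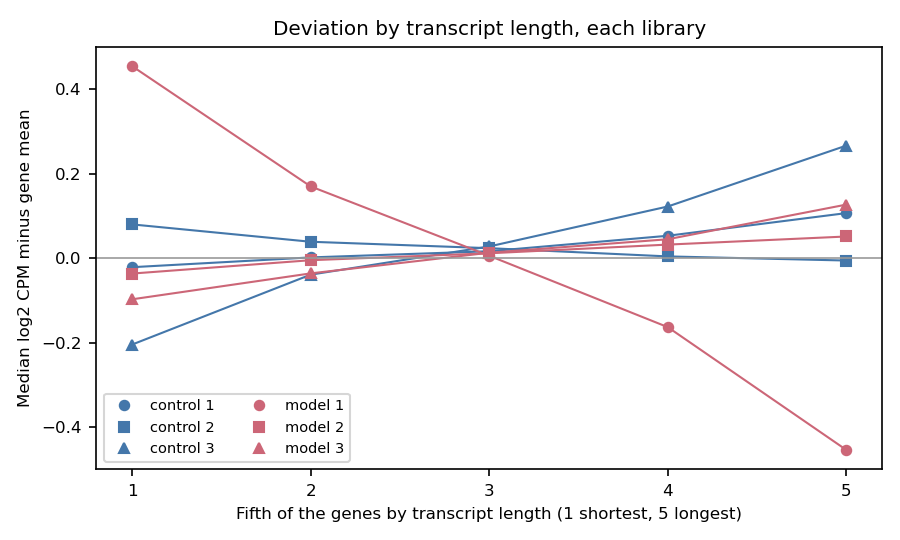
Genes in 5 equal groups by transcript length on the x axis, against the median log2 CPM minus the gene's mean over the 6 libraries; each line is 1 library, blue for control and red for model. In model 1 the median falls from 0.45 in the shortest group to -0.45 in the longest.

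The remaining epithelial and regulatory lists were not called by camera. Markers of Paneth cells, the antimicrobial cells of the crypt base, had all 12 tested members lower in the model group, with a median of -0.68 (-2.25 for edgeR's fold changes, adjusted p = 0.52 by camera), but differed more within the groups than between them. Lyz1 was at 1250, 10.8 and 3740 CPM in the control libraries and at 43.6, 464 and 503 CPM in the model libraries (log2 fold change -2.31, SE 1.66), and Defa24, whose family shares reads, had a log2 fold change of -2.15 (SE 1.5). Without control 2, in which these genes were lowest, the Paneth list was called lower with a median of -3.30, and without control 3 and model 1 it was called higher with one of 1.95 (adjusted p = 0.0011). Goblet cell markers had a median of -0.13 (-0.23 for edgeR's fold changes, adjusted p = 0.73 by camera), with the mucus genes Fcgbp at -0.070 (SE 0.34) and Muc2 at -1.15 (SE 0.61). Enteroendocrine markers had a median of 0.25 (adjusted p = 0.27), with Chgb at 0.091 (SE 0.42) and Gip at 0.80 (SE 1.12). Tuft cell markers had a median of 0.023 (-0.091 for edgeR's fold changes, adjusted p = 0.92 by camera), with Plcg2 at -0.34 (SE 0.28). Junction genes had a median of 0.046 (0.012 for edgeR's fold changes, adjusted p = 0.96 by camera), with Epcam at 0.062 (SE 0.32), Cdh1 at -0.17 (SE 0.23), Tjp1 at -0.37 (SE 0.32), Ocln at 0.16 (SE 0.18) and Cldn1 at 0.15 (SE 0.84). Injury-associated epithelial genes had a median of 0.12 (adjusted p = 0.16), with Clu at 0.70 (SE 0.78), Ly6a at 0.19 (SE 0.39) and Spp1 called when adjusted over the list alone, and were called without control 3 (0.50). Apoptosis and necroptosis genes had a median of 0.071 (adjusted p = 0.23), with Mcl1 at 0.36 (SE 0.22). Immediate early genes had a median of 0.18 (adjusted p = 0.095), with Zfp36 at 0.50 (SE 0.23) and Fos at 0.53 (SE 0.38), and were called without control 3 (0.22) and without model 2 (0.29), while the median was 0.011 without model 1. Circadian clock genes had a median of 0.13 (adjusted p = 0.13), with Clock at 0.28 (SE 0.25), Bhlhe40 at 0.29 (SE 0.29) and Nr1d1 called when adjusted over the list alone, and were called without model 2 (0.27). For changes in either direction fry gave the clock list an unadjusted p = 0.0037, and its smallest adjusted p over the lists was 0.15. With scaling by library size alone the medians of the tuft, junction, injury, apoptosis, immediate early and clock lists were negative. The median of all genes also moved, from -0.018 to -0.21, so these signs do not show the lists lower relative to other genes. The sex-linked genes, a check on the samples with 4 tested members, held Y-linked reads in all 6 libraries, with Eif2s3y at 49.6 ± 4.16 and 55.8 ± 7.16 CPM and Ddx3y at 49.7 ± 7.70 and 53.1 ± 11.2 CPM.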

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

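Voom with library quality weights, the removal of the transcript length trend, the fits without 2 libraries, every DESeq2 fit that leaves out a library or adds a block, and the counts of other splits were chosen after the data were seen. With edgeR and limma-voom the number of genes called stayed at 0 under every scaling, filter and dispersion setting, without each library, with the block and in the added fits, while DESeq2 called 25 genes, the cause of which was not tested (1031 genes had an unadjusted p under 0.05 in DESeq2 and 765 in edgeR). DESeq2 left 68 adjusted p-values as NA. Leaving out 1 library moved the DESeq2 count between 20 and 101. Of the 10 genes with the smallest p, 9 were past the threshold with DESeq2. Scaling by library size alone moved the median log2 fold change of all genes to -0.21, against -0.018 in the main test, and the share of higher values among genes at an unadjusted p under 0.05 was 37.9% in the main test, 25.9% with upper-quartile scaling and 15.3% with library size alone. That share ranged from 25.1% without control 1 to 61.3% without control 3 over the fits without 1 library, and was 54.6% without control 3 and model 1 and 47.1% without control 3 and model 3. Correlations of deviations between libraries of the same number were -0.16, -0.26 and 0.30, and only for number 3 was this the best match. The numbers thus gave no clear sign of a pairing. Deviations within a group are not independent and single libraries stand apart, so these few correlations cannot exclude one. With the replicate block edgeR called 0 genes and camera 23 lists, 21 of them shared with the fit without a block and the other 2 those of Paneth (median -2.18, adjusted p = 0.00020) and adipocyte genes (-2.28, adjusted p = 0.0055), and the 25 DESeq2 genes shared 13 with the blocked DESeq2 fit.

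Of the 21 called lists, 0 were called by camera with an estimated correlation and 0 by fry, both of which allow for members of a list that move together in a library. Without each library in turn camera called between 17 and 22 lists, and 10 of the 21 kept their call and direction each time. Of these, 7 also kept both without control 3 and model 1, without control 3 and model 3, and with the length trend removed: p53 targets, MHC class II, T cell markers, smooth muscle, cholesterol synthesis, fatty acid oxidation and glucocorticoid response. The other 3 of the 10 lost their call without control 3 and model 1: enterocyte (median 0.13), xenobiotic metabolism (-0.18) and heat shock genes (0.20). These calls are at the preset correlation, and some were kept at a smaller size: without control 3 and model 1 the fatty acid median was 0.22 against 1.35 and the cholesterol median -0.42 against -0.83, and without control 3 and model 3 the smooth muscle median was -0.41 against -0.74. For the 3 lists that lost their call, the medians with every library were 1.01 (enterocyte), 1.35 (xenobiotic metabolism) and 0.35 (heat shock). There the median itself was smaller or turned its sign. Fewer libraries also leave less power in both fits without 2 libraries, so a lost call alone does not show a smaller change. Some lists not called with every library were called in these 2 fits. Without control 3 and model 1 they were injury (0.68), interferon gamma (0.43), inflammatory (0.30), Paneth (1.95), endothelial (0.41) and tuft genes (-0.36), and without control 3 and model 3 injury (0.62), interferon gamma (0.30), inflammatory (0.28), goblet (0.23) and plasma cell genes (0.35). With library size alone 3 calls were lost, B cell, fibroblast and neuron and glia. In that setting camera called injury genes higher relative to other genes (adjusted p = 0.037), although their median was -0.070. With the length trend removed the fibroblast call was lost.

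Medians of 6 called and 20 uncalled lists changed sign under at least 1 alternative. Single genes were followed for 23 of the named genes, those with the smallest p and the tested fixed genes. None of the 23 was called by edgeR, and the log2 fold changes of 8 changed sign. Other named genes, such as further list members, were not followed through the alternatives. The cause of the sign changes was not tested. Without control 3 and model 1 the median was 0.70 for B cell, 0.24 for fibroblast, -0.18 for xenobiotic, -0.089 for mitochondrial, -0.024 for oxidative stress and -0.074 for MHC class I genes, all 6 called with every library. In the same fit it was 1.95 for Paneth, -0.36 for tuft, 0.90 for Peyer's patch, 0.045 for dendritic cell, 0.11 for innate sensing, 0.037 for type I interferon, 0.28 for antimicrobial, -0.25 for enteroendocrine, 0.10 for goblet and -0.00069 for apoptosis genes, and log2 fold changes were 0.00619 for Mki67, 0.057 for Tjp1 and 0.35 for Tlr4. Without control 3 and model 3 the values were 0.12 for type I interferon, 0.047 for Peyer's patch, 0.54 for antimicrobial, -0.24 for tuft, -0.18 for clock, 0.23 for goblet and 0.63 for Paneth genes and 0.12 for Tlr4. With library size alone they were -0.024 for immediate early, -0.15 for endothelial, -0.13 for macrophage, -0.12 for apoptosis, -0.073 for clock, -0.20 for tuft, -0.067 for interferon gamma, -0.16 for junction, -0.14 for inflammatory and -0.070 for injury genes, -0.070 for Tnf, -0.0405 for Ocln and -0.14 for Cldn1. In that setting the median of all genes moved from -0.018 to -0.21, so these signs go with a shift of all genes. The replicate block gave -0.066 for tuft, 0.023 for mast cell and -0.030 for junction genes and -0.59 for Tnf. Limma-voom gave -0.20 for Il10 and -0.60 for Tnf, quality weights 0.19 for Tlr4, upper-quartile scaling -0.00856 for Tnf and length removal -0.0051 for junction genes. Leaving out 1 library gave ranges of -0.30 to 1.39 for Cldn1, -0.28 to 0.56 for Il1b, -1.16 to 0.15 for Tlr4 and -0.91 to 0.63 for Tnf. Medians ranged from -3.30 to 1.01 for Paneth, -0.68 to 0.31 for Peyer's patch, -1.04 to 0.099 for antimicrobial, -0.051 to 0.27 for clock, -0.26 to 0.34 for endothelial, -0.40 to 0.27 for goblet, -0.076 to 0.33 for inflammatory, -0.022 to 0.50 for injury, -0.60 to 0.035 for innate sensing, -0.54 to 0.43 for interferon gamma, -0.097 to 0.087 for junction, -0.30 to 0.36 for macrophage, -0.21 to 0.41 for mast cell, -0.21 to 0.33 for plasma cell, -0.20 to 0.42 for tuft and -0.36 to 0.22 for type I interferon genes. Without a change of sign they ranged from 0.055 to 0.59 for enteroendocrine, -0.55 to -0.062 for dendritic cell and 0.018 to 0.19 for apoptosis genes.

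The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The edgeR count of 0 called genes is met by all 10 splits by construction (highest other 1), so that comparison says nothing. Its 765 genes at an unadjusted p under 0.05 were met by 5 splits (highest other 1410). The 25 DESeq2 calls were met by 4 splits, the real one included (highest other 114). The 21 called lists were met by 1 split, the real one (highest other 20, lowest 8). The split with 114 DESeq2 genes sets control 1, control 3 and model 3 against the rest and points to a structure of the libraries other than their groups. Each library has at least 35007515 counts, and which genes the depth limits was not tested beyond Il6 and Ifng, which had too few counts for the test.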

Other observations

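The tests of position for control 3, of GC content for model 1, and of control 3, model 1 and time of day for the glucocorticoid genes were chosen after those results were seen.

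Among the 25 DESeq2 calls, beyond those named above, were genes of several tissues and functions, given here after their values were seen. Casq2, a calcium store protein of muscle, had a log2 fold change of -1.32 (SE 0.32, DESeq2 adjusted p = 0.033), in the same direction as Flnc and the smooth muscle list. Pla2g4c, a phospholipase, had one of -3.02 (SE 0.66, adjusted p = 0.0095 in DESeq2). Slc34a2, a phosphate transporter, had one of -6.92 (SE 1.71, DESeq2 adjusted p = 0.038), but its groups overlapped: it was at 589 CPM in control 3, 54.4 CPM in control 1 and 1.04 CPM in control 2. Col7a1, an anchoring fibril collagen, had one of 1.69 (SE 0.41, DESeq2 adjusted p = 0.033). The immunoglobulin variable segments Ighv11-2, Igkv4-79 and Igkv5-37 were also called higher, with values that reads shared between segments make uncertain. EdgeR called none of these genes. Of the 6 DESeq2 fits that left out 1 library, Casq2, Slc34a2 and Col7a1 were called in 1 each. Igkv4-79 and Igkv5-37 were called in 3 each, Pla2g4c in 4 and Ighv11-2 in 5.

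Control 3 stood apart from the other 5 libraries, with a mean Spearman correlation of 0.931 with them against 0.949 to 0.970 for the others. A bias by transcript length is argued against, since after removal of each library's length trend control 3 still had the lowest mean correlation, 0.935. A tissue piece from further along the small intestine is a candidate explanation: Fabp6 was 4090 times its highest value in the other 5 libraries. The median deviation of proximal genes from their means was -6.20 log2 units, while every other library was above 1. These means include control 3, whose low value by itself raises the deviations of the other libraries, so the latter are no separate evidence. Whether a different piece was taken, or a sample was mislabelled, is not recorded in the labels, and no biological explanation in the design was tested for a single library.

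Long transcripts were low in model 1. GC content is argued against as the cause, since the correlation with length given GC content was -0.409. Within the gene lists, after taking out each list's median, the correlation was -0.454 over 552 genes. It therefore did not come only from shifts of whole lists. A different mix of cell types stays open, because the lists used include pathways, whose members need not share a cell type. A loss of long transcripts whatever the gene may account for the pattern in model 1. Among the 7684 genes that varied least over the other 5 libraries the correlation was -0.558. The other libraries ranged from -0.112 to 0.412 in the same genes. These genes were chosen without model 1, while the deviations are from means that include it. That can favour a large value in model 1 and opposite values in the other libraries, so the size of this contrast is not independent evidence. Fragmented RNA or a difference in library preparation stay open, as the labels give no measure of RNA quality.

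Glucocorticoid response genes as a list were higher in model 1 and model 3 and not in model 2. Both of these technical explanations, the position of control 3 and the lost long transcripts of model 1, are argued against as the whole cause, since the list's median log2 fold change was 0.786 without control 3, and 0.785 without model 1, the smaller of the values without model 1 and with the length trend removed, with camera's call kept each time at its preset correlation, although with all libraries the call is lost at an estimated correlation (adjusted p = 0.51). A different time of day at dissection cannot be told apart from a response to the treatment, because the difference between both arms of the clock was -0.185 log2 units (control -2.349, SD 0.113, model -2.534, SD 0.342) with overlapping groups, although the arm of opposite phase alone was higher in every model library (6.203 to 6.441) than in the controls (5.931 to 6.111) and the day-phase arm overlapped. The genes of both arms were chosen after values of some clock genes had been seen. Among those was Nr1d1, at 2.48 to 5.05 CPM in the control libraries and 12.5 to 14 CPM in the model libraries. A hormone response beyond the list also stays open: a second set of 8 glucocorticoid-induced genes had a median of 0.133, with 6 higher in the model group and 0 separating the groups. Stress at handling, and the treatment itself as a biological explanation, remain hypotheses that these libraries did not test.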
